A study of Gallus gallus with 14 samples.

How the data were processed

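Circular RNAs (circRNAs) are covalently closed transcripts made by back-splicing, in which a downstream splice donor joins an upstream acceptor. Per the labels' protocols, total RNA was extracted from chicken spleen, ribosomal RNA was removed, and linear RNA was digested with RNase R, an exonuclease that spares circles. Strand-specific paired-end libraries were then sequenced on an Illumina HiSeq instrument. RNase R efficiency can vary between libraries, and no spike-in or linear RNA level was used here to check it. Per the submitters' processing notes, Bowtie2 2.2.8 and Bowtie were used. The circRNA caller, the genome build and the filters are not given in the sources used here.

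The deposited table holds raw read counts per circRNA for 2169 circRNAs in 14 libraries. A second set of columns, with TPM in the header, holds values that equal the count times 1000000 over the column total of the same table. All 30366 of these values matched that formula within 0.0001, so the deposited values are CPM (reads per 1000000 reads in the table) with no length term. They are relative to the circRNA reads in the table and not to the whole library. The depth of the whole library is therefore unknown, and an overall rise or fall of circRNA against linear RNA cannot be read from these values. The table holds 0 counts of 1. Its smallest count above 0 is 2 and every circRNA has reads in at least 5 libraries, so a value of 0 can stand for a single read. A circRNA seen in fewer than 5 libraries is not in the table. The circRNAs carry only running numbers, up to 17213. The table pairs them with 0 host genes or positions, so the host gene list tests planned before the data were examined were not run, and no gene function is assigned to any circRNA.

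Libraries were grouped by the labels into tumorous (n = 4), noninfected (n = 5) and survivor (n = 5). The total was between 31383 and 89840 circRNA reads per library. Of the 14 libraries, 4 had at most 45436 reads (tumorous replicate 3 and survivor replicates 1, 2 and 5), and the other 10 had at least 55302. The median circRNA had between 5 and 15 reads per library, so counting error is large for most circRNAs. Reads carry no molecular identifiers here, and intervals and floors cover counting error only. Counts of all 26 pairs of libraries within groups differed by more than sampling noise, with a smallest chi-square per degree of freedom of 3.54, so no library was treated as a duplicate.

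The counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM normalization) in R 4.3.3. All 14 libraries entered one fit with 3 group means, without covariates. The 2098 circRNAs with at least 5 reads in at least 4 libraries were tested, and 71 were left out. Adjusted p-values are Benjamini-Hochberg values over the tested circRNAs, with a threshold of 0.05. Values per group are CPM as mean ± SD. The standard error (SE) of a log2 fold change was derived as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Where a whole group is listed at 0, the fold was computed against a floor of 3 reads per library and given as a lower bound. This bound uses the mean of the other group and leaves out its counting error, so at few reads it is approximate. Totals, circRNAs detected and the share of reads in the 10 most abundant circRNAs were compared with exact two-sided permutation tests, adjusted over the 3 pairs of groups. Detection meant at least 2 reads after thinning each library to 31383 reads (mean of 100 draws). Per the rule fixed before the data were examined for a table without hosts or positions, the 2 circRNAs of smallest p in each direction of each comparison were named, with the 3 most abundant circRNAs. Any other circRNA named was chosen after its values were seen.

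The edgeR step was tested on simulated data. Counts were drawn from the real means, library totals and dispersions of the tested circRNAs, with 200 of them changed and counts of 1 set to 0, in 5 draws per comparison. For the comparison of tumorous with noninfected libraries, run on a mean of 2025 circRNAs, 57.8% of 4-fold and 10.5% of 2-fold changes were recovered, and 3.16% of calls were false. For tumorous against survivor libraries, 56.6% and 7.78% were recovered, and for survivor against noninfected libraries 56.7% and 16.4%, on 2021 and 2028 circRNAs. Each circRNA was drawn independently, with no outlying library and no circRNAs that vary together. These rates may therefore not hold for the real libraries.

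Alternatives fixed before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma 3.58.1 (voom), fits of 2 groups alone, the replicate number as a block, sex or day as a covariate, female libraries alone, other thresholds, and leaving out each library in turn. Alternatives added after the data were seen were thinning of all libraries to 31383 reads, libraries above 50000 reads alone, zeros set to 1 read, tumorous and noninfected libraries limited to days 37 to 43 with the survivors kept, and a share without the most variable of the abundant circRNAs.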

Results

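Marek's disease is a lymphoproliferative disease of chickens caused by a herpesvirus, Marek's disease virus (MDV), which transforms T cells. The study profiled circRNAs in spleens at different outcomes of MDV infection. Chickens received 2000 plaque-forming units of the GA strain of MDV or 0.2 mL of diluent. Spleen libraries were labelled tumorous (n = 4, infected, days 31 to 42) or survivor (n = 5, infected, all day 55), and the 5 diluent libraries (days 37 to 49) are called noninfected here. The labels file these days under days post infection but write them as days of age. The replicate-5 noninfected and replicate-4 survivor libraries were from males and the others from females. No label states that libraries within a group came from separate birds, although days and sex differ between some, so p-values measure the spread between these libraries.

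The table listed 2169 circRNAs, of which 1027 (47.3%) had reads in every library. Total circRNA reads were 61014 ± 23188 (SD, n = 4) in tumorous, 60162 ± 23220 (SD, n = 5) in survivor and 74337 ± 8816 (SD, n = 5) in noninfected libraries. No difference in totals between groups passed the test (exact permutation tests on log2 totals, adjusted p between 0.381 and 0.992). At a common depth of 31383 reads, 1752 ± 83.7 (SD, n = 4), 1800 ± 23.6 (SD, n = 5) and 1806 ± 22.1 (SD, n = 5) circRNAs were detected in tumorous, survivor and noninfected libraries. No difference in these numbers passed the test (exact permutation tests, adjusted p between 0.393 and 0.667), and their order depended on the number of reads that counted as detection.

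The most abundant circRNAs took a smaller share of the circRNA reads in tumorous spleens. The 10 most abundant circRNAs took 12.9% ± 0.988 of the reads in tumorous libraries (SD, n = 4), 16.6% ± 2.13 in survivor libraries (SD, n = 5) and 19.7% ± 1.88 in noninfected libraries (SD, n = 5). Every tumorous library, at 11.9% to 13.9%, lay below every other library. The difference of tumorous from noninfected libraries was -6.78 percentage points (exact permutation p = 0.00794, the smallest that these groups allow, adjusted p = 0.0238). From survivor libraries it was -3.65 points (exact permutation p = 0.0159, adjusted p = 0.0238). Without novel_circ_0006627, chosen after the data were seen, these differences were -4.66 and -2.37 points (exact permutation, adjusted p = 0.0238 for both). The survivor share differed from the noninfected share by -3.14 points (exact permutation p = 0.0397, adjusted p = 0.0397). This difference lost its call when 50 circRNAs were counted in place of 10 (adjusted p = 0.0873), in female libraries alone (0.0571) and without novel_circ_0006627 (0.0635). It was also lost when any of noninfected replicates 1, 2 and 4 or survivor replicates 2, 3, 4 and 5 was left out, with adjusted p from 0.0286 to 0.0873 over all alternatives.

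**Figure D1:**
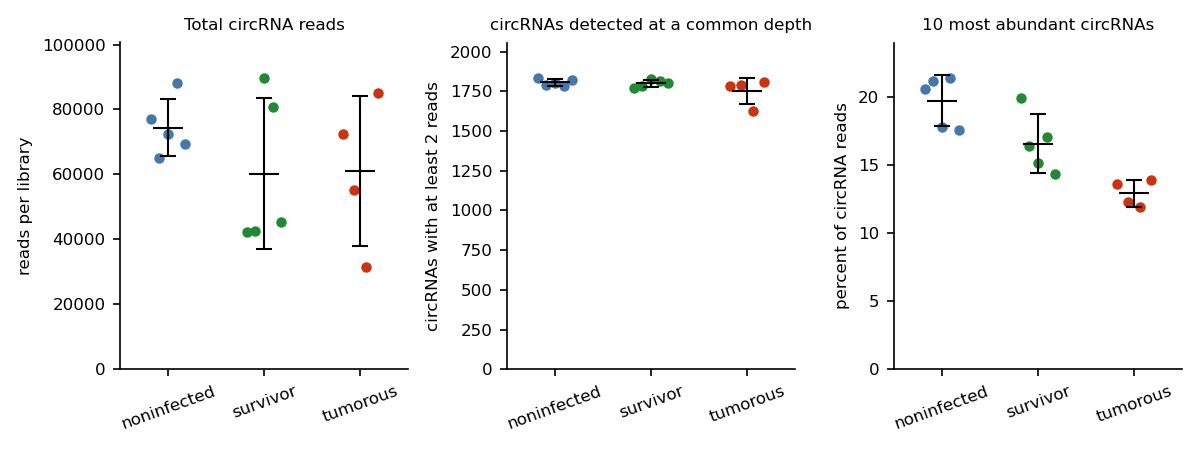
Total circRNA reads, circRNAs with at least 2 reads after thinning to 31383 reads, and percent of reads in the 10 most abundant circRNAs, by group. Each point is a library, the long tick is the mean and the bar the SD; the 4 tumorous libraries have the lowest shares, between 11.9% and 13.9%.

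The 3 most abundant circRNAs were novel_circ_0003067, novel_circ_0006627 and novel_circ_0000394, with 2.77%, 2.14% and 2.08% of the reads on average over the 14 libraries. This order pools groups that differ, and the most abundant circRNA of tumorous replicates 2 and 3 and survivor replicate 5 was none of these. novel_circ_0003067 stood at 18034 ± 6322 CPM in tumorous (SD, n = 4), 25260 ± 4330 in survivor and 37946 ± 8478 in noninfected libraries (SD, n = 5 each). Its fall in tumorous against noninfected libraries passed the test (log2 fold change -1.19, SE 0.25, edgeR adjusted p = 0.00574). novel_circ_0000394 also fell (log2 fold change -1.26, SE 0.30, edgeR adjusted p = 0.0145), but this call was lost with day as a covariate (edgeR adjusted p = 0.0883) and with both groups limited to days 37 to 43 (0.0550). Over its alternatives the adjusted p was between 0.00214 and 0.0883. novel_circ_0006627 was the most variable of the 3. It ranged from 7354 to 81146 CPM among the noninfected libraries and from 701 to 6745 CPM among the tumorous ones, and its log2 fold change of -3.13 (SE 0.97) did not pass (edgeR adjusted p = 0.0799). DESeq2 (adjusted p = 0.00361), limma voom (0.0341) and edgeR with its default filter (0.0494) called it, and over all its alternatives the adjusted p was between 0.000151 and 0.169.

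Tumorous libraries were on average more alike than they were like noninfected libraries. Rank correlations of log2 CPM across circRNAs averaged 0.76 among tumorous libraries, 0.74 among noninfected and 0.73 among survivor libraries. Between groups they averaged 0.65 for tumorous with noninfected, 0.68 for tumorous with survivor and 0.71 for survivor with noninfected libraries. The ranges overlapped, with a lowest value of 0.726 among tumorous libraries and a highest of 0.744 for tumorous with noninfected. The survivors were not uniform. Survivor replicate 5 averaged 0.73 with tumorous and 0.65 with noninfected libraries. Survivor replicates 3 and 4 averaged 0.68 and 0.69 with tumorous and 0.75 each with noninfected libraries. Circular RNAs within one library are not independent replicates, and these correlations describe the libraries only. The first principal component, with 25.4% of the variance, placed the tumorous libraries between 6.51 and 47.3 and the noninfected libraries between -20.3 and -12.1. Survivor replicates 1 to 4 lay between -9.31 and -2.56, and survivor replicate 5 lay at 14.4, within the tumorous range. Within the tumorous group this component rose as read totals fell, from 6.51 at 84926 reads to 47.3 at 31383. Survivor replicates 1, 2 and 5, with few reads, also lay above survivor replicates 3 and 4. The noninfected libraries did not follow this order. The component may therefore partly reflect depth.

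**Figure D2:**
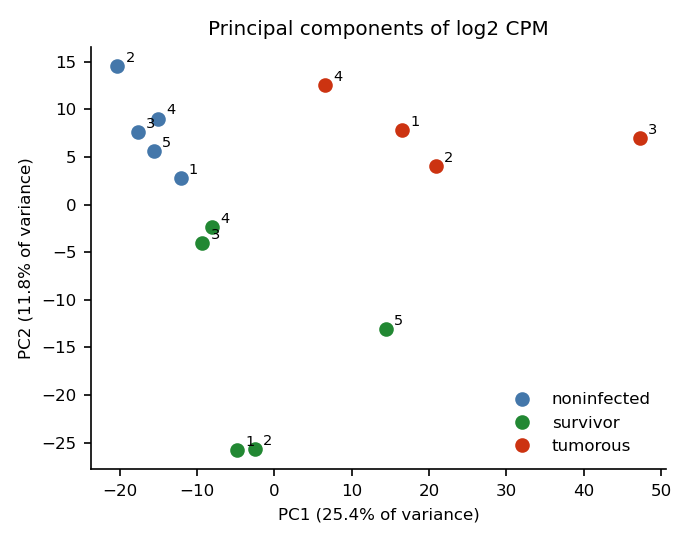
First and second principal components of log2 CPM (prior count 2) for the 14 libraries, numbered by replicate and coloured by group. Tumorous libraries lie at PC1 of 6.51 or more and noninfected libraries at -12.1 or less, with survivor replicate 5 at 14.4.

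The first comparison asked which circRNAs differ between tumorous and noninfected spleen. All tumorous libraries came from infected birds and all noninfected ones from birds given diluent, so infection and tumour cannot be told apart here. Of 2098 circRNAs tested, 149 (7.10%) differed between tumorous and noninfected libraries, 85 higher and 64 lower in tumorous spleens (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The higher circRNAs had a median log2 fold change of 1.73 (quartiles 1.42 and 2.53), and 32 of them were at least 4-fold higher by the fit. The lower ones had a median of -1.73 (quartiles -2.68 and -1.26), and 25 of them were at least 4-fold lower. The 10 called circRNAs listed at 0 in a whole group have fitted values that depend on the prior count. With these set at their lower bounds, the medians were 1.72 and -1.59, and 30 and 18 circRNAs were at least 4-fold higher and lower. As a share of the circRNA pool, the 85 higher circRNAs made up 12.6% ± 2.75 of the reads in tumorous (SD, n = 4) and 4.12% ± 0.294 in noninfected libraries (SD, n = 5). The 64 lower ones made up 7.50% ± 2.30 in tumorous (SD, n = 4) and 16.7% ± 2.02 in noninfected libraries (SD, n = 5). Both sets were chosen on these libraries, so the shares describe their size and are not separate evidence.

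The circRNA of smallest p among those higher in tumorous spleens was novel_circ_0016532. It stood at 1640 ± 738 CPM (SD, n = 4) against 198 ± 90.8 CPM in noninfected libraries (SD, n = 5), with a log2 fold change of 2.85 (SE 0.36, edgeR adjusted p = 0.000106). novel_circ_0015815 rose from 381 ± 101 to 1635 ± 267 CPM (log2 fold change 1.94, SE 0.28, edgeR adjusted p = 0.000484). Among the lower ones, novel_circ_0017004 fell from 1011 ± 472 to 178 ± 55.8 CPM (log2 fold change -2.58, SE 0.39), and novel_circ_0015650 fell from 2863 ± 641 to 564 ± 368 CPM (log2 fold change -2.41, SE 0.37). Both had an edgeR adjusted p of 0.000484. The survivor means of all 4 lay between the tumorous and noninfected means, at 477 ± 184, 704 ± 235, 456 ± 157 and 1901 ± 767 CPM in that order. These 4 were picked as extremes of the tumorous and noninfected groups, so another group tends to lie between them by that choice. Their survivor means are therefore no evidence that survivors are intermediate.

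Some called circRNAs had reads on one side of this comparison alone. Since every listed circRNA has reads in at least 5 libraries, one present in the 4 tumorous libraries alone cannot be in the table, while one present in the 5 noninfected libraries alone can, so the numbers in each direction cannot be compared. 3 were listed at 0 in all 5 noninfected libraries, and except for novel_circ_0002209 they were singled out after their values were seen. novel_circ_0009435 had 35 to 65 reads in each tumorous library, or 808 ± 270 CPM (SD, n = 4), which was at least 19.8-fold higher than the floor of 3 reads per noninfected library (edgeR adjusted p = 0.0206). novel_circ_0009437 had 6 to 9 reads in each tumorous library and was at least 3.16-fold higher (edgeR adjusted p = 0.00795). Both were listed at 0 in survivor replicates 1 to 4 and had 18 and 2 reads in survivor replicate 5. With 0 reads in noninfected libraries, the table could list them only if some survivor had reads. The third, novel_circ_0002209, had 5 to 13 reads in the tumorous libraries and was at least 3.84-fold higher (edgeR adjusted p = 0.00401). In the other direction, 7 called circRNAs were listed at 0 in all 4 tumorous libraries.

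Of the 2098 circRNAs, 283 (13.5%) had no overlap between the tumorous and noninfected libraries, against 1.59% for a random split of 4 and 5. Calls were more frequent among abundant circRNAs, with 71 of 525 in the highest quartile of mean CPM and 13 of 525 in the lowest, where the median SE was 0.81 against 0.32. With library totals as the only scaling, the split of calls was 106 higher and 50 lower, with upper quartile factors it was 77 and 75, and with DESeq2 113 and 114. With totals alone the median log2 fold change of all tested circRNAs was -0.00 in place of -0.13. The count was 227 with DESeq2, 70 with day as a covariate and 77 with the tumorous and noninfected libraries limited to days 37 to 43 and the survivors kept in the fit. It was 82, 91, 90 and 97 without tumorous replicates 2 and 3 and noninfected replicates 2 and 4. Among the libraries above 50000 reads, 105 circRNAs were called. The libraries below held 1 tumorous and 0 noninfected spleens, too few for a value of their own.

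**Figure D3:**
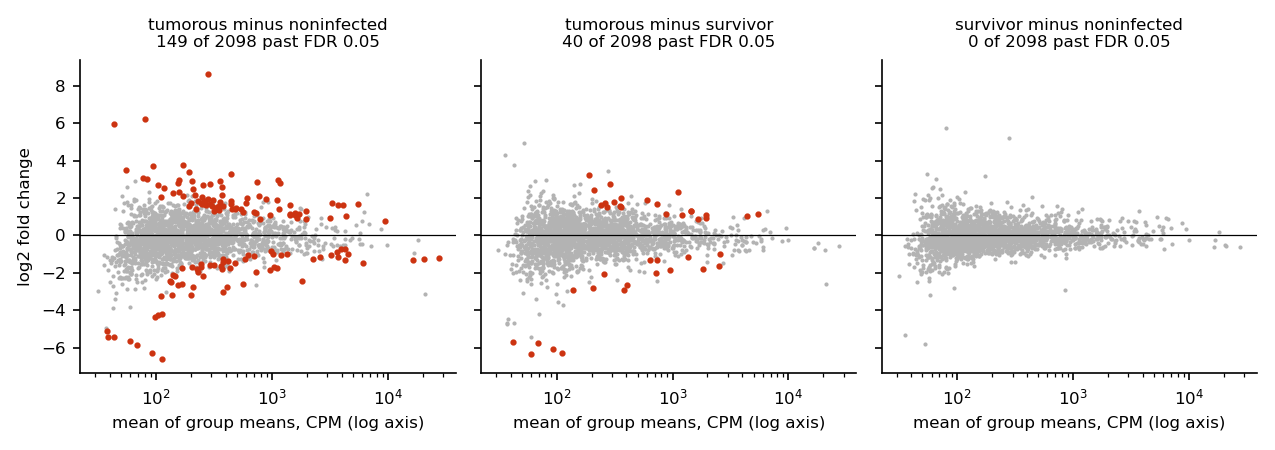
Log2 fold change from the edgeR fit against mean CPM (log axis) for 2098 circRNAs in the 3 comparisons. Red points pass an adjusted p of 0.05, which 149, 40 and 0 circRNAs do; fold changes of circRNAs listed at 0 in a whole group depend on the prior count.

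The second comparison set tumorous spleens against infected birds that survived. 40 of 2098 circRNAs (1.91%) differed, 22 higher and 18 lower in tumorous spleens (edgeR, adjusted p under 0.05). The median log2 fold change was 1.53 for the higher and -2.36 for the lower circRNAs. Of the lower ones, 5 were listed at 0 in all 4 tumorous libraries, and with these at their bounds the median was -1.53. novel_circ_0014457 stood at 1214 ± 317 CPM in tumorous (SD, n = 4) and 312 ± 110 CPM in survivor libraries (SD, n = 5), a log2 fold change of 1.87 (SE 0.32, edgeR adjusted p = 0.00752). novel_circ_0010374 stood at 2433 ± 124 and 910 ± 266 CPM (log2 fold change 1.33, SE 0.24, edgeR adjusted p = 0.00794). On the lower side, novel_circ_0007848 stood at 365 ± 70.1 and 1247 ± 472 CPM (log2 fold change -1.84, SE 0.32, edgeR adjusted p = 0.00752). novel_circ_0004678 stood at 1407 ± 814 and 3920 ± 817 CPM (log2 fold change -1.62, SE 0.31, edgeR adjusted p = 0.0104). novel_circ_0014457, novel_circ_0010374 and novel_circ_0007848 also passed the test in the same direction against noninfected libraries, and novel_circ_0004678 did not (log2 fold change -0.86, SE 0.30, edgeR adjusted p = 0.0926).

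Groups did not overlap for 170 of the 2098 circRNAs (8.10%), against 1.59% for a random split. The count of 40 rested on single libraries. It was 83 without survivor replicate 5, of which 39 were among the 40. It was 12, 8 and 20 without tumorous replicates 1, 2 and 3, and 17, 25, 13 and 23 without survivor replicates 1, 2, 3 and 4. Female libraries alone gave 8, the 2 groups fitted alone gave 22, and DESeq2 gave 115. Libraries above 50000 reads, with survivor replicates 3 and 4 alone, gave 37, of which 22 were among the 40. That set also leaves out survivor replicate 5, so its count does not isolate the effect of depth. With library totals as the only scaling, 33 calls were higher and 17 lower in tumorous spleens, with upper quartile factors 17 and 20, and with limma voom 39 and 15. All survivors were sampled on day 55 and all tumorous birds by day 42, so day and outcome cannot be told apart in this comparison.

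The calls of the first and second comparisons overlapped. 33 circRNAs passed both tests in the same direction, 21 higher and 12 lower in tumorous spleens, and 0 passed in opposite directions. Independent lists of these sizes would share 0.891 higher and 0.549 lower circRNAs. Both comparisons use the same tumorous libraries. In 50 simulations with no effect, 0 circRNAs were shared in any, but the simulated lists held 0.02 and 0.04 calls on average, so this gives no chance value for lists of 149 and 40. The overlap was 72 with DESeq2, 17 in fits of 2 groups, 5 in female libraries and 50 with zeros set to 1 read, and without single libraries it was between 6 (without tumorous replicate 2) and 63 (without survivor replicate 5). With the tumorous libraries split 2 and 2, so that each comparison had its own, between 0 and 10 circRNAs were shared over the 6 splits, mostly with fewer calls in each list. The splits that shared 0 had 2 and 1 calls against survivors. For the splits that shared 10, independent lists would share 0.210 higher and 0.136 lower circRNAs, or 0.129 and 0.036. The fold changes of the 2 comparisons had a correlation across circRNAs of 0.76 and a covariance of 0.77, against a mean of 0.59 and 0.225 in the simulations. With the tumorous libraries split, the correlation was 0.28 to 0.46 and the covariance 0.511 to 0.740.

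The third comparison set survivors against noninfected birds. 0 of 2098 circRNAs passed (edgeR, smallest adjusted p = 0.142). At an unadjusted p under 0.05 there were 165 circRNAs, where 104.9 are expected by chance. DESeq2 called 6 and limma voom 1. The 2 circRNAs of smallest p that were higher in survivors were novel_circ_0015924, at 1042 ± 411 against 331 ± 148 CPM (SD, n = 5 each; log2 fold change 1.58, SE 0.33, edgeR adjusted p = 0.142), and novel_circ_0002209. The latter had reads in 4 of 5 survivors, at most 16 per library, and was listed at 0 in all 5 noninfected libraries. This made it at least 2.37-fold higher (edgeR adjusted p = 0.142). On the lower side, novel_circ_0005414 averaged 97.9 CPM in noninfected libraries, from only 4 to 12 reads per library. It was listed at 0 in all 5 survivors, at least 1.76-fold lower (edgeR adjusted p = 0.157). novel_circ_0009799 stood at 557 ± 194 against 1228 ± 264 CPM (log2 fold change -1.20, SE 0.30, edgeR adjusted p = 0.177). DESeq2 called all 4 of these.

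Survivor and noninfected libraries did not overlap for 45 circRNAs (2.14%), against 0.794% for a random split of 5 and 5. The median SE of a log2 fold change was 0.53. In data simulated for this comparison on 2028 circRNAs, 16.4% of 2-fold and 56.7% of 4-fold changes were recovered. Without survivor replicate 1, novel_circ_0015924 and novel_circ_0002209 passed, and without noninfected replicate 3 novel_circ_0015924 passed. In libraries above 50000 reads, with survivor replicates 3 and 4 alone, 1 circRNA passed, novel_circ_0013118, lower in survivors and named after its values were seen. That the first comparison gave 149 calls and this one 0 does not by itself show that tumorous spleens and survivors differ, which the second comparison tested.

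**Figure D4:**
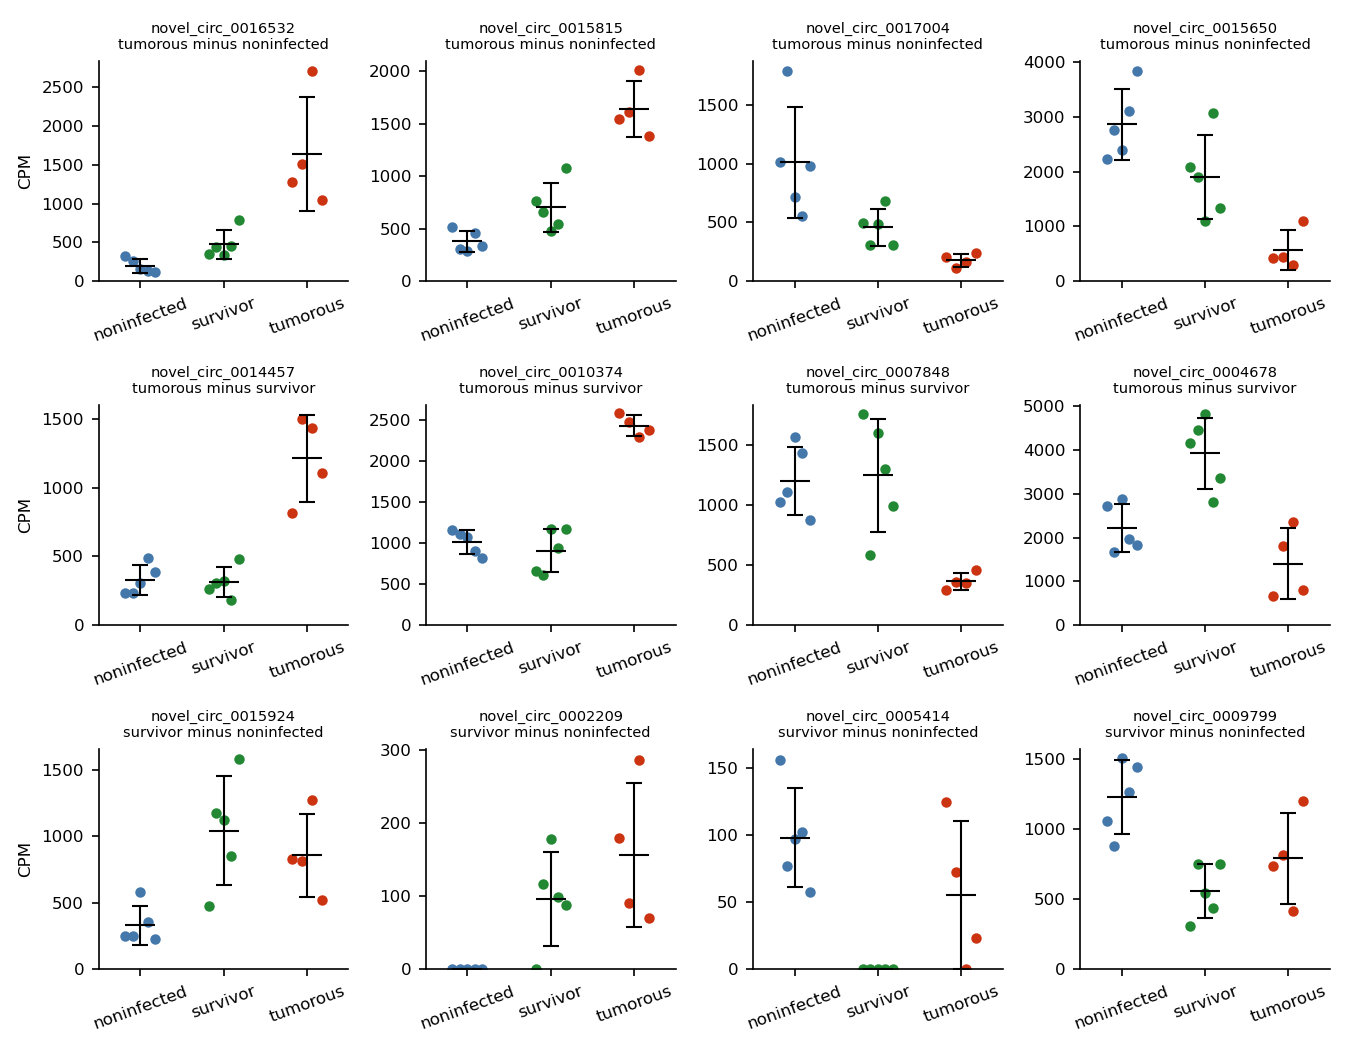
CPM per library of the 2 circRNAs of smallest p in each direction of each comparison, by group. Points are libraries, the long tick is the mean and the bar the SD; novel_circ_0010374 stood at 2433 CPM in tumorous libraries on average against 910 in survivors, and novel_circ_0005414 was listed at 0 in all 5 survivors.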

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

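The tests of survivor replicate 5 in this part were chosen after the results they concern were seen; the counts over other splits of the libraries were planned. Over 58 groups of values examined for a library far from its group, 5 were found. Independent groups of normal values would give about 1 in 20, or 2.9, by chance. The groups examined overlap, and many hold circRNAs picked in these libraries, so 2.9 is a rough guide only.

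Survivor replicate 5 stood out from the other survivors in 3 of the 5 found. Its first principal component was 14.4, against -9.31 to -2.56. Its level of novel_circ_0016532, the circRNA of smallest p between tumorous and noninfected spleens, was 792 CPM against 334 to 458 CPM in the other survivors. Its score on the circRNAs called between tumorous and noninfected libraries, a set chosen without any survivor library, was 0.717 against 0.142 to 0.304. On this score 0 is the noninfected and 1 the tumorous mean, and each tumorous or noninfected library was scored on circRNAs called without it. The tumorous libraries scored 0.506 to 1.30 and the noninfected ones -0.0993 to 0.165. The 3 values overlap, since each separates tumorous from noninfected libraries, and they are not separate findings. Each passed narrowly: the gap from survivor replicate 5 to the nearest survivor was 0.715, 0.729 and 0.718 of the survivor range, against a limit of 0.710.

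Circular RNAs higher and lower in tumorous than in noninfected libraries gave survivor replicate 5 similar scores, 0.693 and 0.739. A low read total argues little for this pattern: survivors 1 and 2 had as few reads, the higher of them lay 0.413 lower, and at equal depth survivor 5 still scored 0.669. A swap would need 1 tumorous library at the level of the other survivors, and the score above left this open, with a gap of 0.202 between the lowest tumorous library and survivors 1 to 4 against a margin of 0.25, while a score on circRNAs chosen between these 8 libraries without the one scored, tried after that gap was seen, argued against it, with tumorous libraries at 0.598 to 1.10, survivors 1 to 4 at 0.109 to 0.245 and a gap of 0.354. A single tumorous library labelled as survivor cannot be told apart from a survivor with tumour-like tissue: novel_circ_0009435, listed at 0 in all other survivors and noninfected libraries, stood at 396 CPM in survivor 5 (exact Poisson 95% interval 235 to 626), below the tumorous range of 553 to 1147 but with an overlapping interval, and the table could list it only because 1 survivor or noninfected library had reads. That this bird carried a spleen lesion, or that tumour RNA entered its library, may also account for it, and neither was tested.

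Of 100 splits of the 9 tumorous and noninfected libraries, 1 (the real one) reached its 149 calls, and the highest other gave 30. Between tumorous and survivor libraries, 2 of 100 splits gave 40 or more, the real one included, and the highest other gave 60. That other split set survivors 1 to 4 against the tumorous libraries joined by survivor 5, which points to a structure of the samples. Both shares of splits were low, which argues against chance for these 2 counts but cannot exclude it. The shares are not adjusted over the 3 comparisons. For tumorous against survivor libraries, that other grouping gave more calls than the labels did. Between survivor and noninfected libraries the count was 0, which all 100 splits reach by construction (highest other 1), so this count cannot argue for or against chance. At an unadjusted p under 0.05 there were 165 circRNAs, which 2 of 100 splits reached, the real one included, with a highest other of 170.

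Tumorous replicate 3 had 1628 circRNAs detected at the common depth, against 1782 to 1810 in the other tumorous libraries. It was the shallowest library and the only one not thinned. Noninfected replicate 2 had the lowest score of its group, -0.0993 against 0.0977 to 0.165.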

How the results depend on the processing

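Leaving out 1 library at a time gave 82 to 177 calls between tumorous and noninfected libraries (149 with all), 8 to 83 between tumorous and survivor libraries (40), 0 to 2 between survivor and noninfected libraries (0), and 6 to 63 calls shared by both tumorous comparisons (33). DESeq2 gave 227, 115, 6 and 72 for these. The shared calls were 17 in fits of 2 groups, 5 in female libraries and 50 with zeros set to 1 read. For tumorous against noninfected libraries the count was 70 with day as a covariate and 77 with both groups limited to days 37 to 43 and survivors kept. For tumorous against survivor libraries it was 93 at an adjusted p of 0.1, 22 in a fit of the 2 groups, 8 in female libraries and 66 with zeros set to 1 read. For survivor against noninfected libraries voom called 1 (novel_circ_0005414) and libraries above 50000 reads 1 (novel_circ_0013118). Apart from these and the replicate block, the alternatives kept these counts within 1.5 times. Over all tested circRNAs the replicate numbers showed no pairing of the libraries. 0 of 13 same-numbered pairs had a correlation of deviations over 0.1, and 2 of 14 libraries correlated best with their own number. A pairing that affects few circRNAs cannot be excluded in this way. The replicate block gave 116, 13 and 0 calls and 11 shared calls, and it called novel_circ_0006627 between tumorous and noninfected libraries (log2 fold change -3.31, SE 0.40, edgeR adjusted p = 0.000151). Without the block the SE of this circRNA was 0.97, so part of its spread may follow the replicate number. Differences in circRNAs detected turned positive with detection at 5 reads (40.6, 13.5 and 27.0 more for tumorous against noninfected, tumorous against survivor and survivor against noninfected), and that of survivors reached 2.14 in libraries above 50000 reads. Leaving out libraries gave -73.3 to -12.7, -66.7 to -6.00 and -12.9 to 0.957 for these, and -0.56 to -0.08, -0.18 to 0.30 and -0.55 to -0.27 for log2 totals. The share in the 10 most abundant circRNAs ranged from -7.31 to -6.36, -4.20 to -2.81 and -3.97 to -2.58 percentage points, and the survivor against noninfected difference lost its call with 50 circRNAs (-1.80), in female libraries (-3.78) and without novel_circ_0006627 (-2.29). Of 359 alternative values for 15 fold changes of named circRNAs, 0 reversed, 12 gained a call and 2 lost one, both of novel_circ_0000394 (-1.11 with day as a covariate and -1.30 with days 37 to 43). These circRNAs were picked by smallest p or abundance in these same libraries, so the lack of reversals says little about the other circRNAs. Causes were not tested. The alternatives with thinned libraries, deep libraries, zeros set to 1, days 37 to 43 and the left-out circRNA were chosen after seeing the data, as were those for shared calls other than DESeq2, RLE, filterByExpr and leaving out libraries, and those for named circRNAs with upper quartile factors, other filters, voom, 2 groups or day. Host gene lists were not run, since no hosts were paired with the circRNAs.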

Other observations

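All tests in this part were chosen after the results they concern were seen, except the test of reads counted under both numbers. Fold changes of circRNAs with close running numbers were correlated. The table gives no positions, and the meaning of the numbering is not stated. For neighbours 1 to 2 numbers apart (565 pairs), the log2 fold changes between tumorous and noninfected libraries had a Spearman correlation of 0.469 across pairs. It was 0.155 for neighbours 3 to 10 apart (971 pairs) and 0.073 for those over 10 apart (561 pairs; permutation p = 0.083). Each of the first pair of values lay above all of its 10000 shuffled orders (permutation p = 1e-04, the smallest they can give, adjusted p = 0.00018 over 9 relations), whose largest absolute values were 0.155 and 0.130, which argues against a chance order. For close pairs it was 0.368 between tumorous and survivor and 0.290 between survivor and noninfected libraries. For neighbours over 10 apart it was 0.008 (permutation p = 0.85) and 0.103 (permutation p = 0.014, adjusted p = 0.018) in these comparisons. Between survivor and noninfected libraries the correlation was therefore not confined to close numbers. Pairs of circRNAs are not independent replicates.

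A candidate explanation is that close numbers mark circRNAs of one locus that share its transcription, which cannot be tested without positions. Counting the same reads under both numbers would tie the pairs within groups as well, and the median correlation of group-centred values over the 14 libraries was 0.187 (quartiles -0.07 and 0.43), with 0.354% of close pairs above 0.9. This argues against most close pairs holding the same reads. Random pairs had a median of 0.0174, so close pairs also varied together within groups, and sharing of some reads stays open. Where both members of a pair were called between tumorous and noninfected libraries, 7 of 7 pairs 1 to 2 apart and 7 of 9 pairs 3 to 10 apart had the same direction.

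Whether survivors as a group keep part of the tumorous profile was examined with the score described for survivor replicate 5. The survivor mean was 0.304 ± 0.240 (SD, n = 5) and the noninfected mean 0.090 ± 0.110 (SD, n = 5; two-sided permutation p = 0.0556). Without survivor replicate 5 the p was 0.127 (permutation, 4 against 5). Survivors shared a set of circRNAs, while each noninfected library was scored on its own set. The scores are therefore not fully exchangeable between these groups, and both p-values are approximate. The hypothesis is not decided by these libraries, and day is confounded with the survivor group.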
